A study of Arabidopsis thaliana with 6 samples.

How the data were processed

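Leaf RNA of Arabidopsis thaliana was measured on Affymetrix ATH1 arrays in 2 genotypes, the accession Col-0 as wild type and the T-DNA insertion mutant des1-1, with 3 biological replicates each. Plants were 3 weeks old and grew in soil, per the labels' protocols, and biotin-labelled cRNA was made from total RNA cleaned on columns. The values deposited by the authors are log2 expression values made with RMA and the affy package, per the submitters' processing notes, in which no version is given. RMA subtracts background, brings the arrays to a common distribution and summarises the probes of a probe set. A shift shared by all genes of an array is therefore removed before any comparison, and differences of dim probe sets are compressed. The deposited log2 values carry 2 decimals and ran from 3.63 to 14.63. Arrays have no read depth, and the number of arrays limits the precision.

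The table holds 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests and used for array quality, and the other 22746 were all tested, dim ones included. A platform annotation named 13513 of them with 1 gene, 503 with several and left 8730 unnamed here. No gene was named from a probe set with several. Symbols were updated through the gene identifiers of the TAIR10.1 reference table, which matched 13436 of the 13513. That table was used for names, neighbouring loci and gene span, and no coordinates are given because the build behind the array annotation is not given in the sources used here. DES1 itself lies among the genes without a named probe set, so its own level was not analysed here and the genotype labels were not checked against it.

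Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, two-sided, Benjamini-Hochberg over all 22746 probe sets). Every SE, 95% interval, p and adjusted p of a single gene comes from this limma fit. A gene is said to have risen or fallen in des1-1 where its adjusted p was under 0.05. A looser list took probe sets with an unadjusted p under 0.05 and at least a 2-fold difference. Gene lists with at least 3 measured probe sets were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, each adjusted over the 33 lists tested. The fit was tested on simulated data with 200 changed probe sets among 22746 in this comparison. It recovered 36% of 50 changes of 0.5 on the log2 scale, 88% of 50 changes of 1 and 100% of 50 changes each of 2 and 3, with 8 false calls. Members of the UDP-glycosyltransferase list not among the 200 were also shifted by 0.5 and left out of the false-call count. Noise was drawn independently for each probe set and array. The simulation lacks the structure that real arrays share across probe sets, so these rates do not describe the errors in these data. Tables were joined with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

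The comparison, the tests, 27 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule, among probe sets with 1 gene, names every measured member of the cysteine list as values, and up to 12 genes per direction with the largest difference among those that passed the test with no overlap between genotypes. A direction with fewer than 8 such genes is filled to 8 by size from probe sets with unadjusted p under 0.05 and no overlap, as values. It also names up to 4 members of each fixed list with the smallest unadjusted p. Where a gene had several probe sets, the one with the highest mean was used. Only 63 of the 434 loci on the fixed lists had a probe set with 1 named gene, and 5 of the 27 lists had none (nitrate and phosphate, flowering time, and the markers of flower, of phloem and xylem and of dividing cells). To use more of the array, 21 lists of gene families and genome compartments were added after the data had been seen and before the genotype test was run. Alternatives changed the normalization, the filter on dim probe sets, the eBayes settings, array weights, a replicate block and the arrays included. A fit without wild type 2 and des1-1 3, a fit with a covariate for structure within genotypes, and list tests without SWEETIE, CYP71 and CYP59, which the name patterns had taken into the SWEET and cytochrome P450 lists, were added after seeing the data.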

Results

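The study compared leaves of the des1-1 mutant with leaves of the wild type. DES1 is a homolog of the O-acetylserine(thiol)lyases, the enzymes that make cysteine, and has a role in cysteine homeostasis. The comparison asks which transcripts differ in leaves when DES1 is disrupted. Each of the 3 wild-type and 3 des1-1 arrays gave a log2 value for 22746 probe sets, and the array medians lay between 5.78 and 5.81. Pairs of arrays of 1 genotype correlated at 0.9939 to 0.9966 across probe sets, and pairs across genotypes at 0.9869 to 0.9967.

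The largest rises among named genes in des1-1 were those of AT4G16260, PDF1.2b, PDF1.2 and AT4G12490. AT4G16260, which encodes a putative beta-1,3-glucanase, rose from 5.34 ± 0.18 to 8.06 ± 0.31 (mean log2 value ± SD, n = 3 each), a 6.60-fold rise with an adjusted p of 0.000267 in limma. The plant defensin genes PDF1.2 and PDF1.2b, coding for antifungal peptides that respond to jasmonate and ethylene, rose 4.68-fold (log2 difference 2.23 ± 0.09 SE, adjusted p = 6.92e-05) and 5.40-fold (2.43 ± 0.14 SE, adjusted p = 0.000267). The probe set of PDF1.2b can also bind related transcripts, so the pair may not be 2 independent measurements. AT4G12490, of the lipid-transfer-like family of AZI1, rose 3.95-fold (log2 difference 1.98 ± 0.20 SE, adjusted p = 0.00643).

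Rises of at least 2-fold were also found for AT2G05540 (log2 difference 1.61 ± 0.15 SE), AT3G19550 (1.34 ± 0.10), AT1G49500 (1.14 ± 0.07) and HIS1-3 (1.00 ± 0.10), the last a drought-inducible linker histone. Smaller rises were those of AT4G38540 (1.95-fold), AT3G23550 (1.90-fold), a MATE-type efflux carrier, AT5G58570 (1.88-fold) and UF3GT (1.77-fold), an anthocyanin glycosyltransferase. Adjusted p for these 8 genes ran from 0.000486 for AT1G49500 to 0.0228 for UF3GT. As the rule for named genes required, all 3 des1-1 values lay above all 3 wild-type values in each of these 12 genes that rose.

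Among the named genes that passed, 5 fell. AT1G60590, which encodes a pectin lyase-like protein, had a log2 difference of -0.98 ± 0.14 SE (adjusted p = 0.029), and AT4G28080 one of -0.90 ± 0.13 SE (adjusted p = 0.029). COR15A, a cold-induced protein of the chloroplast stroma, fell from 13.08 ± 0.13 to 12.40 ± 0.08 (mean log2 value ± SD, n = 3 each; adjusted p = 0.0228 in limma). The chloroplast gene ndhH, for a subunit of the NDH complex, fell by 0.64 on the log2 scale (adjusted p = 0.0113), and AT1G67870 fell by 0.52 (adjusted p = 0.0257). The largest lower values with no overlap between genotypes belonged to rpl16 (log2 difference -1.71 ± 0.39 SE), rpl14 (-1.50 ± 0.34) and rpl22 (-1.43 ± 0.36), chloroplast ribosomal protein genes that lie close together by locus number. These 3 did not pass the test (adjusted p = 0.125, 0.127 and 0.143), and their des1-1 arrays were spread widely, with an SD of 0.94 for rpl16 against 0.22 in the wild type.

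**Figure D1:**
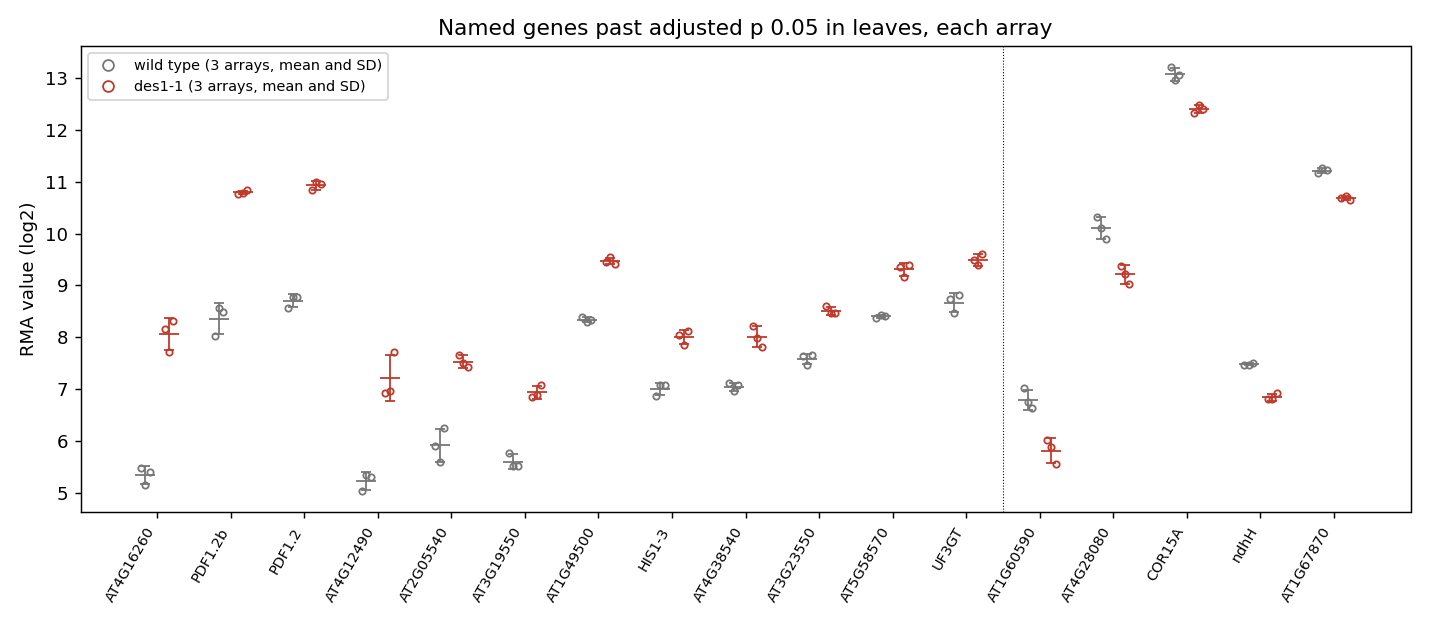
RMA values (log2, vertical axis) of the 17 genes named by size that passed the test, with each of the 3 wild-type arrays (grey) and 3 des1-1 arrays (red) as a point and bars for the mean and SD. The 12 genes left of the dotted line rose and the 5 right of it fell, and in none of them do the genotypes overlap, as the rule for named genes required.

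Over all probe sets, 88 passed an adjusted p under 0.05, of which 75 were higher and 13 lower in des1-1. Without des1-1 1 the balance turned, with 219 higher and 546 lower. With a covariate for structure within genotypes, added after seeing the data, it was 349 and 305. That covariate was made from the residuals, so it left every difference unchanged and took up spread within genotypes. A higher count is largely built into such a fit. Among the 88, 36 carried 1 gene name (30 higher, 6 lower), 3 carried several and 49 were unnamed here. All 24 probe sets that passed the test with at least a 2-fold difference were higher. Among the unnamed probe sets the 2 with the largest rise were 7.03-fold and 5.24-fold higher, and the 2 with the largest fall differed by -0.74 and -0.70 on the log2 scale. Of the 6 named genes that fell, AT1G31690 was not reached by the rule for named genes, and was looked up after its values were seen. One of its probe sets fell by 0.59 on the log2 scale (adjusted p = 0.0427), while its brighter probe set differed by -0.03 (adjusted p = 0.918). At an unadjusted p under 0.05, 3540 probe sets passed (1798 higher, 1742 lower) against 1137 expected of independent tests and up to 1989 in other splits of the 6 arrays, and 40 of these differed at least 2-fold, 25 higher and 15 lower (22 and 60 without des1-1 1, 18 and 5 without des1-1 3). The genotypes did not overlap in 4215 probe sets, 18.5% of those tested against 10% by chance.

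The number of calls rested on single arrays. It was 28, 22 and 20 without wild type 1, 2 and 3, 765 without des1-1 1, of which 28.6% were higher, and 39 and 46 without des1-1 2 and 3, and 9 without wild type 2 and des1-1 3 together. The calls of AT4G16260, PDF1.2, PDF1.2b, AT2G05540, AT3G19550, AT1G49500, HIS1-3, AT3G23550 and AT5G58570 held with any single array left out, whereas those of the other 9 named genes that passed, DFR and all 5 that fell among them, were lost in at least 1 such fit.

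The measured genes of cysteine and sulfur metabolism did not pass the test, and most genes on these lists were not measured. From the cysteine list, 3 of 20 genes were measured, with 3 of 24 from sulfate assimilation. The sulfur deficiency list had 2 of 12 and the glutathione and methionine list 4 of 19. CPNIFS, a plastid cysteine desulfurase, differed by 0.13 (95% interval -0.07 to 0.34), LCD by 0.07 (-0.13 to 0.27) and OASA2 by -0.05 (-0.21 to 0.11), all on the log2 scale. In sulfate assimilation, the ATP sulfurylase genes APS4 and APS3 differed by 0.22 (-0.02 to 0.47) and 0.12 (-0.11 to 0.34), and the sulfite reductase gene SIR by 0.02 (-0.16 to 0.20). Of the sulfur deficiency genes, BGLU28 differed by 0.09 (-0.11 to 0.30) and AT1G04770 by -0.09 (-0.37 to 0.19). BGLU28 and OASA2 were dim, with wild-type means of 4.16 and 4.79 against array lower quartiles of 4.69 to 4.78, where differences are compressed. In glutathione and methionine metabolism MGL stood at 0.18 (-0.02 to 0.37), CBL at 0.17 (-0.04 to 0.37), GR1 at -0.07 (-0.27 to 0.14) and GR at -0.04 (-0.24 to 0.15). Camera gave adjusted p of 0.83 for the cysteine list, 0.436 for sulfate assimilation and 0.727 for glutathione and methionine, and the sulfur deficiency list had too few members to test.

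The flavonoid and anthocyanin list, with 3 of 17 genes measured, stood higher in des1-1, which does not describe the whole pathway. Of its 3 measured genes UF3GT and DFR, the gene of dihydroflavonol reductase (1.65-fold, log2 difference 0.72 ± 0.11 SE, adjusted p = 0.036), rose, and all 3 passed when adjusted over the list alone. The remaining member, AT4G14090, an anthocyanin glucosyltransferase gene, differed by 0.83 ± 0.15 SE (adjusted p = 0.0765 over all probe sets). The list mean was 0.79 higher, with an adjusted p of 2.45e-05 in camera, 0.273 with an estimated correlation and 0.0126 in fry. Each of the 3 des1-1 arrays had a list mean above all wild-type arrays.

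The autophagy list, with 11 of 22 genes measured, was also shifted upward, by a mean of 0.24. Most of the 11 were members of the ATG8 family, whose proteins are attached to the autophagosome membrane. None of the 11 passed over all probe sets in limma, 6 passed at an unadjusted p under 0.05, and 6 passed when adjusted over the list alone. ATG8E differed by 0.56 ± 0.09 SE (adjusted p = 0.0538), ATG8B by 0.45 ± 0.12, ATG8D by 0.38 ± 0.11 and APG8H by 0.30 ± 0.08. ATG3 stood at -0.12 ± 0.11. Camera gave an adjusted p of 0.000382, with 0.745 at an estimated correlation and 0.122 in fry. ATG8E passed the test after quantile normalization (adjusted p = 0.0249), cyclic loess (0.0304) or centring of the arrays (0.0475), within a range of 0.0249 to 0.456 over its 18 alternatives.

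The cold, dehydration and abscisic acid list, with 4 of 16 genes measured, was lower in des1-1. Besides COR15A, which fell, COR15B differed by -0.41 ± 0.09 SE and the dehydrin gene COR47 by -0.31 ± 0.10, and these 3 of the 4 measured genes passed when adjusted over the list alone. LTI30, another dehydrin gene, stood at 0.10 ± 0.10. The list mean was -0.32, with an adjusted p of 0.00805 in camera, 0.502 with an estimated correlation and 0.0163 in fry. Without des1-1 1 the camera call was lost (adjusted p = 0.0674), against a range of 0.00273 to 0.0674 over the alternatives that kept the same list test.

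The lists of the 2 organelle genomes, added after the data had been seen, lay on opposite sides of 0. Of 69 chloroplast probe sets 56 were lower in des1-1, 12 higher and 1 equal, with a median log2 difference of -0.23. In limma ndhH fell, and 18 fell when adjusted over the list alone. The chloroplast list mean was -0.33, with an adjusted p of 1.28e-09 in camera, 0.745 with an estimated correlation and 0.269 in fry. Wild type 2, the array with the high 25S ribosomal RNA control, also had the highest chloroplast list mean, 0.13 above the wild-type mean, with rbcL at 11.48 and psbB at 11.07 against 9.42 to 9.81 and 9.49 to 9.83 on the other arrays. Without wild type 2 the list mean was -0.26 (camera adjusted p = 4.34e-06, within 1.19e-14 to 0.00282 over the alternatives that kept the same list test). Of 23 mitochondrial probe sets, for 16 genes, 20 were higher and 3 rose, a set of cox1 (0.65 ± 0.08 SE, adjusted p = 0.0228) and 2 sets of nad1 (0.64 ± 0.09 and 0.76 ± 0.11 SE, adjusted p = 0.0248 and 0.029), genes of the respiratory chain that were chosen after their values were seen. The other 5 probe sets of nad1 did not pass, with log2 differences of 0.51, 0.25, 0.07, 0.04 and 0.03. When adjusted over the list alone, 8 rose and 2 fell. The mitochondrial mean was 0.20 higher, with an adjusted p of 0.000382 in camera, 0.573 with an estimated correlation and 0.0517 in fry. Leaving out the dimmest 50% of probe sets removed most of this list, 1 of the 2 nad1 sets that rose among them. The mean of the remaining mitochondrial probe sets was 0.33 (camera adjusted p = 0.0159). In all, 5 of the 33 lists passed in camera at the preset correlation, and 0 passed with an estimated correlation. Over all probe sets, 88 passed in limma and 3540 had an unadjusted p under 0.05. For the flavonoid and cold lists the estimated correlations, -0.131 and -0.00937, lay under the preset 0.01. A higher correlation was therefore not what ended the calls of those lists.

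**Figure D2:**
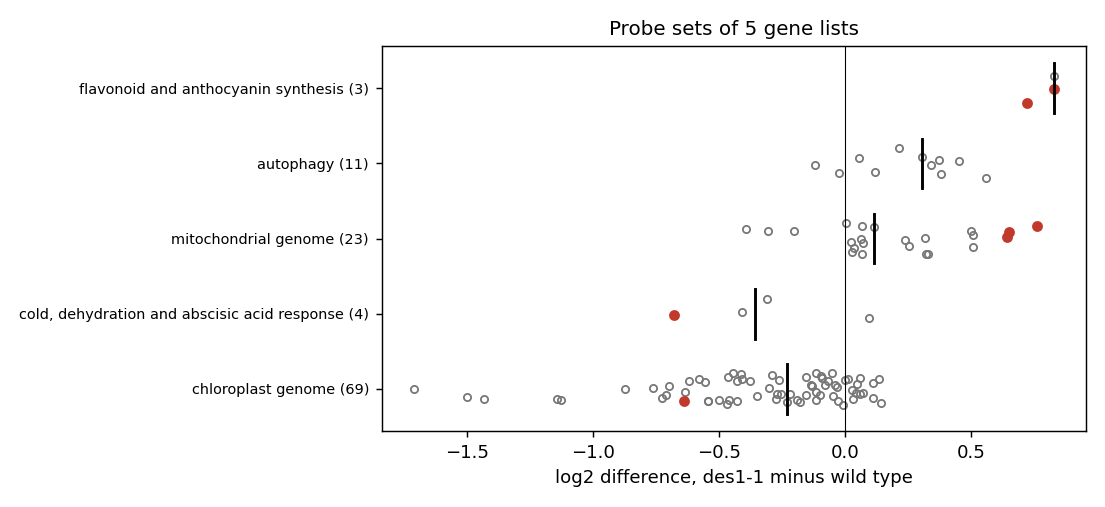
Log2 difference between des1-1 and wild type (horizontal axis) of each probe set in the 5 lists that passed in camera, with the number of probe sets in brackets, red points for those past an adjusted p of 0.05 over all probe sets and black bars at the list medians. The chloroplast values reach down to -1.71 while the mitochondrial ones reach up to 0.76.

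**Figure D3:**
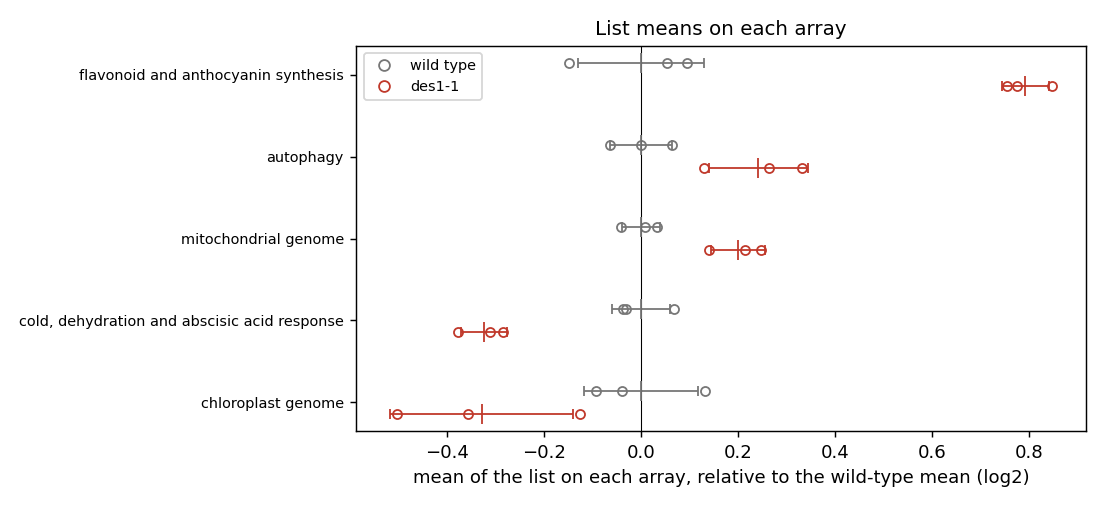
Mean of each of the same 5 lists on each array relative to the wild-type mean (log2, horizontal axis), with 3 wild-type points (grey) and 3 des1-1 points (red) per list and bars for the mean and SD. The chloroplast list ranges from -0.09 to 0.13 on the wild-type arrays. On the des1-1 arrays it ranges from -0.50 to -0.13, the widest spread of the 5 lists on those arrays.

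Other stress and defence genes gave single values. The zinc finger gene STZ, on the oxidative stress and the touch and wound lists, differed by 0.44 ± 0.11 SE (adjusted p = 0.138 in limma), AT2G21640 by 0.35 ± 0.15 and CCS, the copper chaperone of superoxide dismutase, by -0.27 ± 0.10. BCAT4, an enzyme of methionine chain elongation in glucosinolate synthesis, differed by 0.40 ± 0.08 SE, AT2G31790 by -0.14 ± 0.08 and UGT74B1 by 0.06 ± 0.09, and fry but not camera passed that list (adjusted p = 0.0163 and 0.642). On the jasmonate list PDF1.2 rose while BSMT1 stood at 0.05 ± 0.08. BSMT1 was dim, as were GSTU25, BHLH101 and ATHSP22.0 among the genes that follow, with wild-type means of 4.17, 4.26, 4.37 and 4.65. The array lower quartiles were 4.69 to 4.78, and differences of dim probe sets are compressed. SAG101, the only measured gene of the salicylic acid list, stood at 0.16 ± 0.14, GSTU20 at 0.25 ± 0.08, GSTU25 at -0.05 ± 0.08, MT1C at 0.21 ± 0.09 and BHLH101 at -0.07 ± 0.08. The heat shock genes ATHSP22.0, AT1G53540 and AT5G48570 gave 0.08, -0.10 and 0.00 in log2 difference, with intervals of -0.10 to 0.26, -0.35 to 0.15 and -0.29 to 0.28, and the endoplasmic reticulum genes BZIP60 and CRT1b gave 0.17 ± 0.09 and -0.14 ± 0.09.

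Development, photosynthesis and marker lists had no gene past the test. The nuclear photosynthesis genes PRK, LHCB4.2, RCA and LHCB4.1 differed by -0.17 ± 0.08, 0.07 ± 0.09, -0.07 ± 0.08 and 0.04 ± 0.08 SE (camera adjusted p = 0.837). The senescence genes WRKY53, WRKY6 and SAG29 gave -0.04 ± 0.14, -0.03 ± 0.11 and 0.02 ± 0.12 (camera adjusted p = 0.919), and the clock gene GI gave -0.10 ± 0.08. Root markers EXPA7 and EXPA18 stood at 0.04 ± 0.15 and -0.02 ± 0.13. The stomatal lineage markers FMA, MUTE and SPCH stood at 0.16 ± 0.09, 0.17 ± 0.12 and 0.06 ± 0.07 (camera adjusted p = 0.387). MUTE and SPCH were dim, with wild-type means of 4.48 and 4.53. The reference genes AT4G34270 and AT2G28390 differed by 0.06 ± 0.07 and -0.06 ± 0.10. Among 112 measured loci within 100 locus-number steps of DES1 on the chromosome, 0 passed in limma, and their median absolute log2 difference of 0.09 stood at the 44.34 percentile of equally long runs of loci. The percentile was 30.94 within 50 steps and 76.58 within 200 steps, again with 0 loci past the test.

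The arrays also differed within genotypes. The first principal component held -19.56, -14.99 and -7.54 for the wild-type arrays and 1.36, 12.70 and 28.04 for the des1-1 arrays. The 25S ribosomal RNA control read 10.2 on wild type 2 and 5.49 to 6.20 on the other arrays. The 3 prime minus 5 prime signal of the GAPDH control was -0.68 ± 0.05 in the wild type and -0.47 ± 0.13 in des1-1 (SD, n = 3 each), and that of actin was 1.28 ± 0.17 and 1.32 ± 0.08.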

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

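Of the settings below, 3 were chosen after seeing the data: leaving out wild type 2 and des1-1 3 together, a covariate from the first principal component of the residuals, and leaving out list members matched by name prefix only, which kept the same 5 lists. Median centring, quantile normalization and cyclic loess gave 98, 104 and 102 calls against 88 and lost 0 of the 18 named genes that passed. The call count rose to 151 with an intensity trend in eBayes and to 654 with the covariate (349 higher, 305 lower), and dropped to 9, all higher and 0 lower, without wild type 2 and des1-1 3, where 5 of the 18 named genes kept their call. Leaving out single arrays gave 20 to 765 calls, 19 to 219 higher and 0 to 546 lower. The 13 lower calls became 27 without the dimmest 25% of probe sets, 26 without the dimmest 50% and 40 with the trend. The 40 probe sets at least 2-fold apart became 23 to 82 with single arrays left out, of which 5 to 60 lower, 25 with arrays weighted (5 lower), and 21 without wild type 2 and des1-1 3 (2 lower). With an estimated correlation 0 gene lists passed. The beta-glucosidases (0.745 with an estimated correlation and 0.242 in fry over all probe sets) passed in camera as a further list, lower in des1-1, without wild type 2 (camera adjusted p = 0.0464) and without the dimmest 25% or 50% (0.00907 and 0.0159, 7 probe sets each). The pseudogenes (0.972 with an estimated correlation and 0.907 in fry over all arrays) passed in camera, lower in des1-1, without des1-1 2 (camera adjusted p = 0.0185). Deviations of same-numbered arrays correlated at 0.17, -0.23 and 0.21. Replicates 1 and 3 correlated best with their own number, and replicate 2 did not. The first principal component rose with replicate number in both genotypes. With 3 arrays per genotype, these values cannot decide whether replicate numbers pair the arrays. The replicate block gave 183 calls, 94 higher and 89 lower, kept 71 of the 88 and ended the call of DFR (adjusted p = 0.0556). The covariate took up spread within genotypes and left each difference unchanged, so its higher count is largely built in. Beyond this and fewer arrays or probe sets, the cause was not tested.

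Signs turned only for values near 0, none past the test. Over single arrays left out, log2 differences ran from -0.20 to 0.048 for WRKY53, -0.057 to 0.14 for SAG29, -0.15 to 0.090 for AT5G48570, -0.13 to 0.077 for EXPA18, -0.12 to 0.0067 for GR1, -0.11 to 0.082 for WRKY6, -0.14 to 0.16 for EXPA7, -0.027 to 0.083 for SIR, -0.11 to 0.018 for GR, -0.0083 to 0.28 for SAG101, -0.023 to 0.10 for UGT74B1, -0.11 to 0.0067 for RCA and -0.21 to 0.035 for AT1G04770. With arrays weighted WRKY53 stood at 0.085, SAG29 at -0.030 and AT5G48570 at 0.069, the last also at 0.010 after median centring and 0.00018 after cyclic loess. Without wild type 2 and des1-1 3, AT1G04770 and GR1 stood at 0.030, WRKY53 at 0.10, WRKY6 at 0.125, AT5G48570 at 0.055 and LHCB4.1 at -0.005. Dim probe sets limit the size of a difference, and the changes of 0.5 simulated with independent noise were recovered at 36%.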

Other observations

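The counts over other splits of the arrays and the tests of gene span, of spread within genotypes, of 3 prime signal and of chloroplast classes were chosen or their predictions written only after the results had been seen.

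Single genes outside the rule for named genes, chosen after their values were seen, add to the rises in des1-1. AT2G38870, a proteinase inhibitor gene of the potato inhibitor type, rose 1.71-fold (adjusted p = 0.0278 in limma). The ethylene response factor gene AT5G61590 rose 1.62-fold (adjusted p = 0.00643), the bHLH factor gene AT5G50915 1.67-fold (adjusted p = 0.0161), and the calcium-binding EF-hand protein genes AT2G41410 and AT2G46600 rose 1.73-fold and 1.54-fold (adjusted p = 0.029 and 0.011). All 3 des1-1 arrays lay above all 3 wild-type arrays for each of these 5 genes.

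Among families added after the data had been seen, the calmodulin-like proteins (7 probe sets, mean 0.16, camera adjusted p = 0.0962) and the beta-glucosidases (20 probe sets, mean -0.14, camera adjusted p = 0.0962) did not pass over all arrays and probe sets. The beta-glucosidases, at 0.745 with an estimated correlation and 0.242 in fry, passed in camera at the preset correlation in 3 of the alternatives (adjusted p = 0.0464, 0.00907 and 0.0159), the last 2 with 7 of the 20 probe sets. CML41 stood at 0.48 ± 0.13 SE, and BGLU33, BGLU47 and BGLU40 at -0.98 ± 0.21, -0.53 ± 0.13 and -0.62 ± 0.16, values chosen after they were seen. The SWEET list (15 probe sets, camera adjusted p = 0.167) was formed by name and took in SWEETIE (-0.58), which is not a SWEET sugar transporter. Without it, a choice made after seeing the data, the 14 probe sets had a mean of 0.15, with an adjusted p of 0.059 in camera, 0.745 with an estimated correlation and 0.292 in fry, and values of both signs, SWEET17 at 0.49 ± 0.10 and SWEET11 at -0.26 ± 0.07. Of 15 plant defensin probe sets those of PDF1.2 and PDF1.2b rose while 10 were lower, so that the median of -0.05 and the mean of 0.26 differ in sign (camera adjusted p = 0.553, fry adjusted p = 0.0163).

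The count of 88 calls, the 40 probe sets at least 2-fold apart and the 5 gene lists were set against all 10 splits of the 6 arrays into 3 and 3. In each case 1 split, the real one, gave as many, and the highest of the others gave 0 calls, 12 probe sets and 3 lists. With 10 splits the share is never under 0.1, too few for a share under 0.05. The split with 12, which also had 1989 probe sets at an unadjusted p under 0.05 against 3540, put wild type 1, wild type 2 and des1-1 1 against the rest.

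Across 13259 nuclear genes, which are not independent replicates, the log2 difference correlated with gene span at a Spearman coefficient of -0.248, and the difference between the pair of arrays of 1 genotype farthest apart on the first principal component at -0.199 in des1-1 and -0.072 in the wild type. The median difference was 0.0067 in the shortest of 10 span classes, 0.04 in the third and -0.08 in the longest. Each array's median in each class was then taken off. The 8 named genes that rose at least 2-fold kept a median log2 difference of 1.777 (1.80 before, median SE 0.12) and all 8 calls. Class medians of -0.08 to 0.04 could not have brought such differences under the bound of 0.5 set for it, so this outcome was fixed in advance. The values show only that the median trend with span was small beside these rises. The 16 probe sets without a named gene among the 24 were outside this correction. A response of des1-1 plants, or a difference in growth or exposure between the 2 sets of plants, may underlie these 8 rises, and the design holds no test between them.

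The 15 probe sets at least 2-fold lower at an unadjusted p were spread widely within genotypes. Their widest range within a genotype divided by the difference between genotypes had a median of 1.03. None of them passed the adjusted test, which at such differences goes with a wide spread, so this ratio is partly built in. A difference between arrays that also runs within a genotype may account for these 15 probe sets, but the ratio cannot decide it. The same span correction left the 5 nuclear genes among them, AT1G22060, AT1G65010, AT1G19835, AT5G53020 and AT4G37080, at a median of -1.022 (-1.11 before, median SE 0.26). This was not beyond 2 SE of the bound of 0.5 in size set for it. These 5 genes were all long, at span percentiles of 88.31 to 99.33, against 5.102 to 46.61 for the 8 named genes that rose. The median trend was small beside these differences too, at -0.08 in the longest class. The correction takes off class medians only, so it could not decide on span for these 5 genes, and span stays open for them. The other 10 probe sets were outside it. More degraded RNA in des1-1 cannot be told apart from a genotype effect, because the 3 prime minus 5 prime signal moved by 0.04 ± 0.11 SE for actin (the median of the 3 controls), 0.22 ± 0.08 for GAPDH and -0.01 ± 0.06 for ubiquitin. Bacterial control probe sets also varied: the 5 prime sets of dap and thr differed by -0.40 each, those of lys and phe by 0.07 and -0.02. Their 3 prime sets differed by 0.07, 0.06, 0.11 and 0.39 in the same order. The source of these differences was not tested. The genotype itself stays open as an explanation.

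The lower chloroplast transcripts had a widest range of the list mean within a genotype of 1.142 times the difference between genotypes, which is consistent with a difference between arrays that also runs within a genotype. One lower yield of all chloroplast RNA would move its classes alike. Ribosomal protein transcripts (15) differed from photosystem transcripts (20) by -0.3622 ± 0.17 SE (two-sided permutation p = 0.024) over probe sets, which are not independent. The lowest ribosomal protein values, -1.71 to -0.76, belonged to rpl16, rpl14, rpl22, rps3, rpl36 and rps19, which are neighbours by chloroplast locus number. The others ran from -0.41 to 0.14, within the photosystem range of -0.73 to 0.14. The class difference therefore does not describe ribosomal protein transcripts at large. Over arrays the SE was 0.18 and the genotypes overlapped, with -0.05 on des1-1 1 and -0.09 on wild type 2, so a common yield and a change in 1 class cannot be told apart. An effect of the genotype on plastid transcripts stays open and was not tested separately.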
